A study of Mus musculus with 12 samples.

How the data were processed

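RXR and H3K27ac were mapped by ChIP-seq in E14 mouse ES cells and their neural derivatives, 1 peak list per library. The 12 lists fall into 10 groups as the labels give them. These are RXR and H3K27ac in ES cells with control, GW3965, LG268 or RA treatment (1 library each), and RXR at day 8 and day 16 of differentiation (2 libraries each).

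The submitters' processing notes name BWA 0.6.0, HOMER 4.2 and MACS2 2.0.10, and list the builds mm9 and mm10 without a role for each. Per the file headers, the peaks were annotated against mm10. Peaks were called per library. Each peak carries a score given by the authors, whose scale between libraries is not stated. It is used here within a list, with 2 exceptions. The stricter threshold puts the same score cut, 7.65, on every list, and scores of day replicates are combined or compared. The distance to the nearest TSS, the nearest gene and the location class are also deposited values. Peak numbers run higher than the peaks present, with 3.60% to 38.2% of numbers absent per list, by a step the notes do not describe. As a check of the build, the TSS implied by the deposited distance lay within 1000 bp of a gene end of GRCm38.p6 for 7631 of 9421 RXR peaks (81.0%). The lists give no read totals, so depth per library is unknown, and peak number depends on it.

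Peak number, covered length and median width were taken per list. Overlap of at least 1 bp was counted as a share of a list's peaks with an exact (Clopper-Pearson) 95% interval. Chance overlap came from 200 random placements on the same chromosomes with widths kept. A promoter peak lay within 1 kb of a TSS, and promoter shares were compared with the control list by two-sided Fisher's exact test on peaks, Benjamini-Hochberg adjusted. H3K27ac lists of control and ligand were merged to regions called in the ligand only, the control only or both. Regions with a ligand-only RXR peak were compared with regions without RXR by the same kind of test, adjusted over 3 ligands. These tests compare peaks in single lists, and no test compares the treatments as conditions, each with 1 library. Day 8 and day 16 are given as mean and SD of 2 replicates, and a day's regions are those with a peak in both.

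The 12 gene lists were fixed before the data were examined, as were the tests and most alternatives. They hold 9 to 39 genes: retinoic acid receptor, liver X receptor and PPAR targets, and nuclear receptor, pluripotency, neural progenitor, neuronal, Hox, endoderm, mesoderm, glial and trophoblast genes. A gene counted if it was the nearest gene of a peak within 100 kb of its TSS. The background was the 14490 genes named as nearest gene in any of the 12 peak lists. The 10000 random lists of the same size were matched on the number of control H3K27ac peaks. Members outside this background were not counted. It held 21 of the 25 RAR targets, 15 of 23 LXR targets, 19 of 22 PPAR targets and 17 of 39 Hox genes. Counts are given out of these members, so shares of the full lists are lower. A list was above chance if at most 2.5% of random lists had as many genes. Some genes are in 2 lists, such as Hoxb1 and Esrrb, so the lists are not independent.

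Genes were named by a rule. It takes the nearest genes of the 10 highest peaks of each RXR list, of each ligand list without a control peak and of each day, of the 10 highest gained H3K27ac regions with a ligand-only RXR peak, and members of the 12 lists with a peak. Some genes the rule names are not reported here. The 10 highest peaks outside repeats were added after the values were seen, since repeats fill the top. Repeats are peaks annotated as simple repeat, satellite, low-complexity or rRNA element, or on the mitochondrial genome.

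The alternatives were a stricter score threshold, lists of equal length, 50% reciprocal overlap, centres within 200 bp, merging or exclusion within 1 kb, promoters within 5 kb, gene windows of 10 kb or without limit, other backgrounds, each differentiation replicate left out, and a replicate block. Leaving out repeat peaks, a crossed replicate block, ES lists of equal length for the day comparison, the H3K27ac overlap alternatives and gene lists near H3K27ac regions were chosen after the data were seen. The planned scan for nuclear receptor direct repeats was not run, because no genome sequence was used here.

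The overlap count was tested on simulated data: 59.3% was found where 59.2% had been planted in 1089 peaks. On the RA RXR list, the gene list test called 1% of lists of 24 genes without excess and 100% of those with 10 planted peak genes. Shorter gene lists, smaller excesses and the shorter peak lists were not simulated, so a list that did not pass may hold an undetected excess. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and statsmodels 0.14.6 for the Mantel-Haenszel odds ratio.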

Results

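RXR, the retinoid X receptor, is a nuclear receptor that binds DNA as the partner of other receptors such as RAR (retinoic acid receptor), LXR (liver X receptor) and PPAR. The series mapped RXR by chromatin immunoprecipitation and sequencing (ChIP-seq) in E14 mouse embryonic stem (ES) cells and in their neural derivatives. In ES cells RXR was mapped in a control and after 24 h with a ligand at 1 µM. The ligands were GW3965, an LXR agonist, LG268, an RXR agonist, and RA, all-trans retinoic acid, the RAR ligand. Acetylation of histone H3 at lysine 27 (H3K27ac), a mark of active promoters and enhancers, was mapped in the same 4 conditions. RXR was also mapped at day 8 and day 16 of a neural differentiation through embryoid bodies, in which the protocol adds RA at 5 µM. The 12 libraries fall into 10 groups: 8 with 1 library and 2, the differentiation days, with 2 libraries each. The labels do not say that the replicates came from separate cultures, so their spread may be technical. The files give peaks and no read totals, so the depth of each library is unknown and intervals on shares of peaks cover counting error only. All positions are in mm10, as the file headers name it, and gene names are the nearest genes as annotated in the files.

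In control ES cells the nearest genes of the 10 highest RXR peaks outside repeats were Scd3, Scd2, Abcg1, Scd1, Fasn, Srebf1, Iqck, Plekhb1, 4930522O17Rik and 1700001O22Rik. Peaks outside repeats are named because repeats fill the top of every RXR list, a choice made after the values were seen. The peak upstream of Scd2, a stearoyl-CoA desaturase gene, had a score of 76.8 and rank 13 of 1089 (chromosome 19, 44284049 to 44284539, intergenic). Abcg1, a sterol exporter, carried a peak in intron 2 of 14 with a score of 63.3 (chromosome 17, 31073317 to 31073705). Fasn, the fatty acid synthase gene, carried a promoter peak with a score of 59.0 (chromosome 11, 120824584 to 120825066). The Scd3 and Scd1 peaks lay 44995 and 18968 bp from the TSS. Of the 15 LXR target genes in the background, 9 had a control peak within 100 kb of the TSS, against a mean of 1.22 in random gene lists and 0 of 10000 lists with as many. Of 21 RAR target genes 11 had a peak, against 1.66 by chance, with Rarb at its promoter (score 33.0, chromosome 14, 16575357 to 16575765) and both Cyp26a1 and Cyp26b1, enzymes that degrade RA. Of 19 PPAR target genes 9 had a peak, against 1.21 by chance, Cpt1a and Angptl4 among them. Nuclear receptor and cofactor genes (6 of 23) and Hox genes (5 of 17) also lay above chance, with 110 and 8 of 10000 random lists as high. The nuclear receptor call ended with peaks within 10 kb (3 genes). Pluripotency, neural progenitor and neuronal genes had no control RXR peak, where chance gave 1.29, 1.55 and 1.29 genes. The endoderm (2 genes), mesoderm (1), glial (3) and trophoblast (1) lists did not pass the chance level. Of the 10 highest peaks of the control list, 9 lay in the telomere-type simple repeat (TTAGGG)n, and 153 of its 1089 peaks (14.05%) lay in simple repeats, satellites, low-complexity or rRNA elements or on the mitochondrial genome. The score is the authors' value and is used within a list, apart from the stricter threshold and where scores of day replicates are combined or compared.

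The first comparison asks whether a ligand changes how many RXR sites are found in ES cells. The LG268 list held 2089 RXR peaks and the RA list 1970, against 1089 in the control and 940 with GW3965. The ratios to the control were 1.92 for LG268, 1.81 for RA and 0.863 for GW3965. Covered length followed the numbers, with 256 kb in the control, 237 kb with GW3965, 554 kb with LG268 and 500 kb with RA. The median peak width was 216 bp in the control and 225, 241 and 233 bp with GW3965, LG268 and RA. With 1 library per treatment no test between treatments was possible and a difference in depth cannot be told from a difference in binding.

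**Figure D1:**
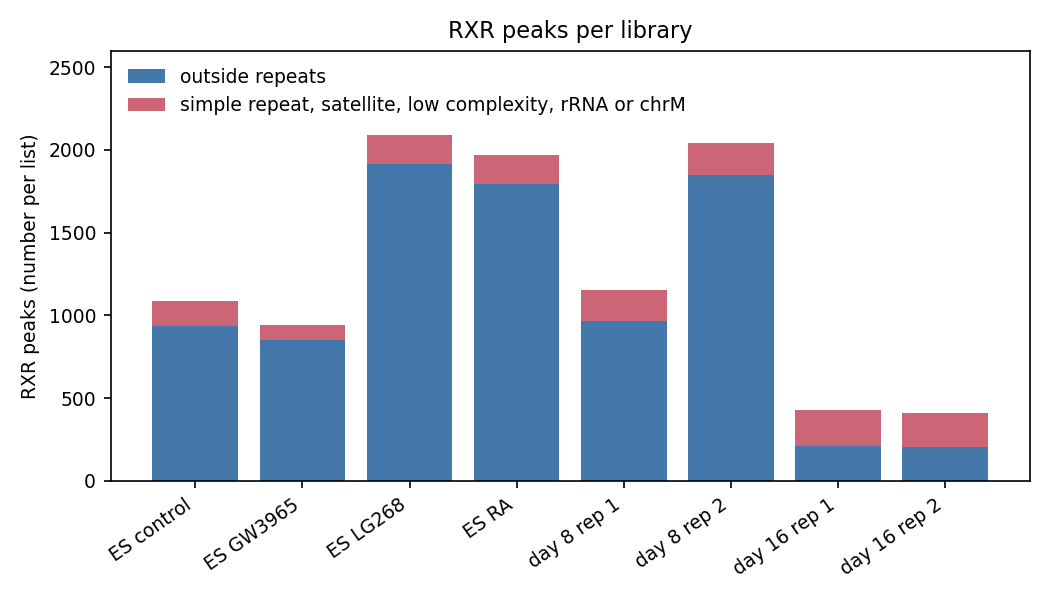
Number of RXR peaks in each of the 8 RXR lists, 1 bar per library, with the peaks in repeats or on the mitochondrial genome stacked above those outside. The LG268 (2089) and RA (1970) lists hold more peaks than the control (1089), and repeats hold 217 of 429 and 204 of 409 peaks in the day 16 lists.

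The RXR sites of control cells were largely found again with LG268 and RA, and mostly not with GW3965. Of the 1089 control peaks, 72.5% (exact 95% interval 69.7 to 75.1) overlapped an LG268 peak by at least 1 bp, 72.0% (69.2 to 74.6) an RA peak and 22.6% (20.1 to 25.2) a GW3965 peak. LG268 and RA shared 54.5% of the LG268 peaks (52.3 to 56.6) and 57.9% of the RA peaks (55.7 to 60.1), while 31.7% of the GW3965 peaks were found with LG268 and 31.5% with RA. Placement at random on the same chromosomes gave 0.103% for control peaks in the LG268 list and 0.0216% in the GW3965 list. Merging the 4 lists gave 3701 regions, of which 218 had a peak in every list, 450 in control, LG268 and RA, and 423 in LG268 and RA alone. A further 811 regions had a peak with LG268 alone, 693 with RA alone, 599 with GW3965 alone and 179 in the control alone. With repeat peaks left out there were 3539 regions. Of these, 127 had a peak in every list, 388 in control, LG268 and RA, and 412 in LG268 and RA alone. Regions of a single list were then 805 for LG268, 693 for RA, 607 for GW3965 and 185 for the control. The 6 LXR targets Abca1, Abcg1, Fasn, Scd1, Scd2 and Srebf1 had a peak in all 4 lists. So did the PPAR targets Acaa2, Angptl4, Cpt1a and Slc25a20, the RAR targets Cyp26b1 and Rarb, and Ncoa3, a nuclear receptor coactivator gene. Random placement at control H3K27ac peak centres in place of random positions lowered the excess for control peaks in the LG268 list from 701 times to 28.8 times chance.

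**Figure D2:**
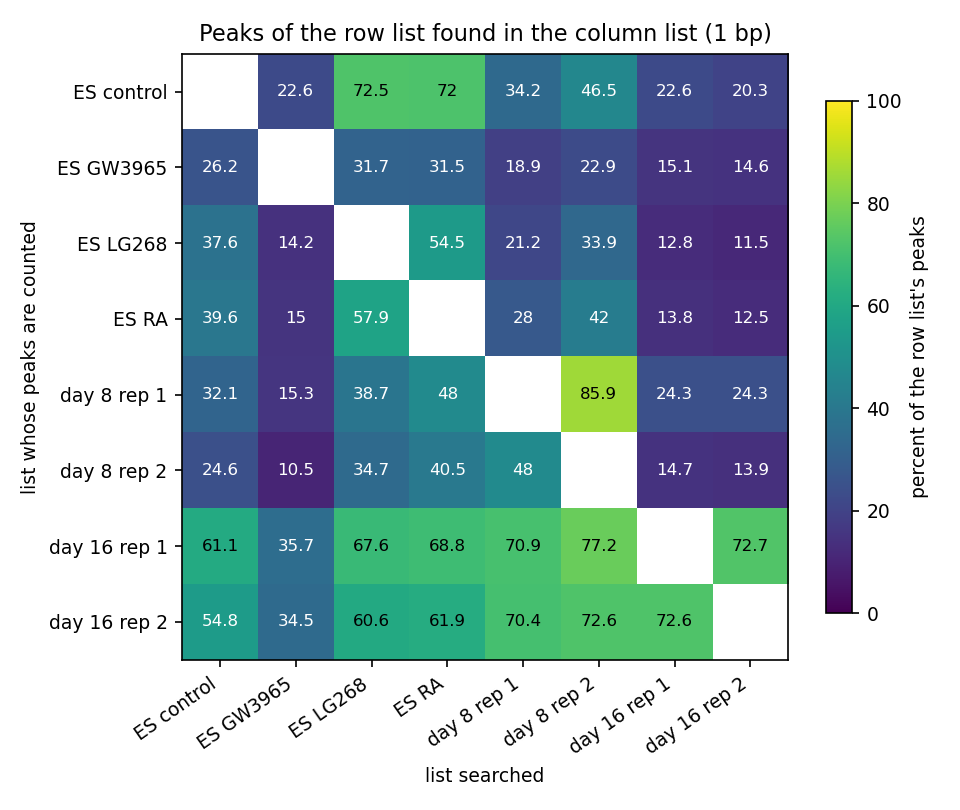
Percent of the peaks of each RXR list (rows) that overlap a peak of each other RXR list (columns) by at least 1 bp. Control peaks are found in the LG268 and RA lists at 72.5% and 72.0% and in the GW3965 list at 22.6%, and the day 8 replicate 1 list is found in day 8 replicate 2 at 85.9%.

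The RA list had a peak near 19 of the 21 RAR targets in the background, against 2.87 by chance and 0 of 10000 random lists as high, and 11 in the control. The 8 genes with a peak with RA and none in the control were Dhrs3, Hoxb1, Meis1, Meis2, Nrip1, Rai1, Stra6 and Tshz1, and no RAR target had a control peak without an RA peak. Over all 14490 background genes, 1498 had an RA peak and 860 a control peak, so a longer list alone adds genes. The count of RAR targets cannot exceed the 21 in the background, of 25 on the fixed list. Their growth and that of the list therefore cannot be compared as ratios. Of the other lists above chance with RA, LXR targets had 8 genes against 9 in the control and PPAR targets 11 against 9. Hox genes had 6 against 5 and endoderm genes 5 against 2. The difference between RA and control was not tested. With lists of equal length the counts of RAR targets were 14 and 10. The highest RA peak outside repeats was assigned to Dhrs3, a retinal reductase gene, with a score of 95.9 (chromosome 4, 145034550 to 145035015, intron 64 of 68 of an overlapping transcript, 141645 bp from the Dhrs3 TSS). Rarb had a promoter peak with a score of 54.8. Of the 1970 RA peaks, 1189 (60.4%, interval 58.2 to 62.5) had no control peak. The highest of these lay nearest to Skap1, Dmr, Mir1901, Qk, Tshz1, Aldh3a2, Tbc1d5, Tmem161b, Meis2 and Hoxa2. The LXR (8 of 15), PPAR (11 of 19), Hox (6 of 17) and endoderm (5 of 12) lists were above chance, with 2, 0, 33 and 93 of 10000 random lists as high. The nuclear receptor (5), neural progenitor (3), neuronal (3) and glial (4) lists were not, and pluripotency, mesoderm and trophoblast genes had no RA peak. The endoderm call ended with peaks within 10 kb (1 gene) and with lists of equal length (2 genes). Limited to the control's number of peaks, 43.4% of the RA list had no control peak.

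With LG268, the RXR agonist, peaks lay near 13 of 21 RAR targets, against 2.98 by chance, and each of these 13 also had an RA peak. Dhrs3, Meis2, Nrip1 and Rai1 had a peak with LG268 and none in the control, and 6 RAR targets had an RA peak and no LG268 peak: Hoxb1, Meis1, Rara, Stra6, Stra8 and Tshz1. This difference between 2 single libraries was not tested. LG268 peaks lay near 9 of 15 LXR targets, with Npc1 added to the control set and Lpl missing from it, and near 11 of 19 PPAR targets, with Klf10 among those added. The 10 highest LG268 peaks outside repeats lay nearest to Scd3, Scd2, Elovl5, Fasn, Srebf1, Cpt1a, Plekhb1, Guca2b, Scd1 and Abcg1. Elovl5 is a fatty acid elongase gene (score 77.1) and Cpt1a encodes a carnitine palmitoyltransferase of fatty acid oxidation (59.6). Of the 2089 LG268 peaks, 1303 (62.4%, interval 60.3 to 64.5) had no control peak, and the highest of these lay nearest to Hoxa2, Grk5, Acadl, Mbd6, 4933402J10Rik, Zfand5, 4930517E11Rik, Klf10, Pcnxl4 and Fignl1. Of these, the peaks at Grk5, 4933402J10Rik and 4930517E11Rik lie in repeats. The RAR, LXR and PPAR lists each had 0 of 10000 random lists as high, the nuclear receptor list (8 of 23) had 137, the Hox list (6 of 17) 49 and the endoderm list (5 of 12) 160. The other 6 lists did not pass: pluripotency (1, Sox2), neural progenitor (3), neuronal (1, Mnx1), mesoderm (0), glial (3) and trophoblast (1). The endoderm call ended under all 4 other settings. Limited to the control's number of peaks, 43.9% of the LG268 list had no control peak.

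With GW3965, the LXR agonist, RXR peaks lay near most LXR targets of the control list and near pluripotency genes. LXR targets had peaks at 8 of 15 genes, against 1.13 by chance and 0 of 10000 random lists as high, with Mylip, a sterol-regulated ubiquitin ligase gene, added to the control set and Arl4c and Lpcat3 missing from it. The highest peaks outside repeats lay at Scd3, Fasn (score 44.4, rank 12 of 940), Scd2, Wnt10a, Srebf1, 4930522O17Rik, Abcg1, Scd1, Asb4 and Aida. Of 20 pluripotency genes 8 had a GW3965 peak, against 1.09 by chance and 0 of 10000 random lists as high, and none of the 8 had a peak in the other 7 RXR lists. This is 1 library, and it differs from the other ES lists in its LTR share as well, 16.4% of peaks against 2.48% in the control. The 8 genes were Pou5f1, Klf2, Esrrb, Zfp42, Tbx3, Tfcp2l1, Prdm14 and Utf1. Zfp42 had a score of 22.3 and rank 29 (chromosome 8, 43320723 to 43321002, intergenic, at -13853 bp from the TSS). The Pou5f1 peak lay at -1993 bp from the TSS with a score of 10.7 and rank 160 (chromosome 17, 35503923 to 35504156), and the Esrrb peak in intron 3 of 6 with a score of 13.1 (chromosome 12, 86501663 to 86502015). PPAR targets had peaks at 7 of 19 genes, with 0 of 10000 random lists as high. RAR targets had peaks at 5 of 21 genes (152 of 10000), with Cyp26b1, Rarb, Dhrs3 and Aldh1a2 among them, a call that ended with peaks within 10 kb (2 genes) and with no distance limit (5 genes). The nuclear receptor (3), neural progenitor (1), neuronal (1) and Hox (2) lists did not pass, and endoderm, mesoderm, glial and trophoblast genes had no GW3965 peak. Of the 940 GW3965 peaks, 694 (73.8%, interval 70.9 to 76.6) had no control peak. The highest of these lay nearest to Asb4, Apol7a, Zfp42, F5, Jam2, 4931440L10Rik, Fam227b, Mettl20, Rbm14 and 2510009E07Rik.

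**Figure D3:**
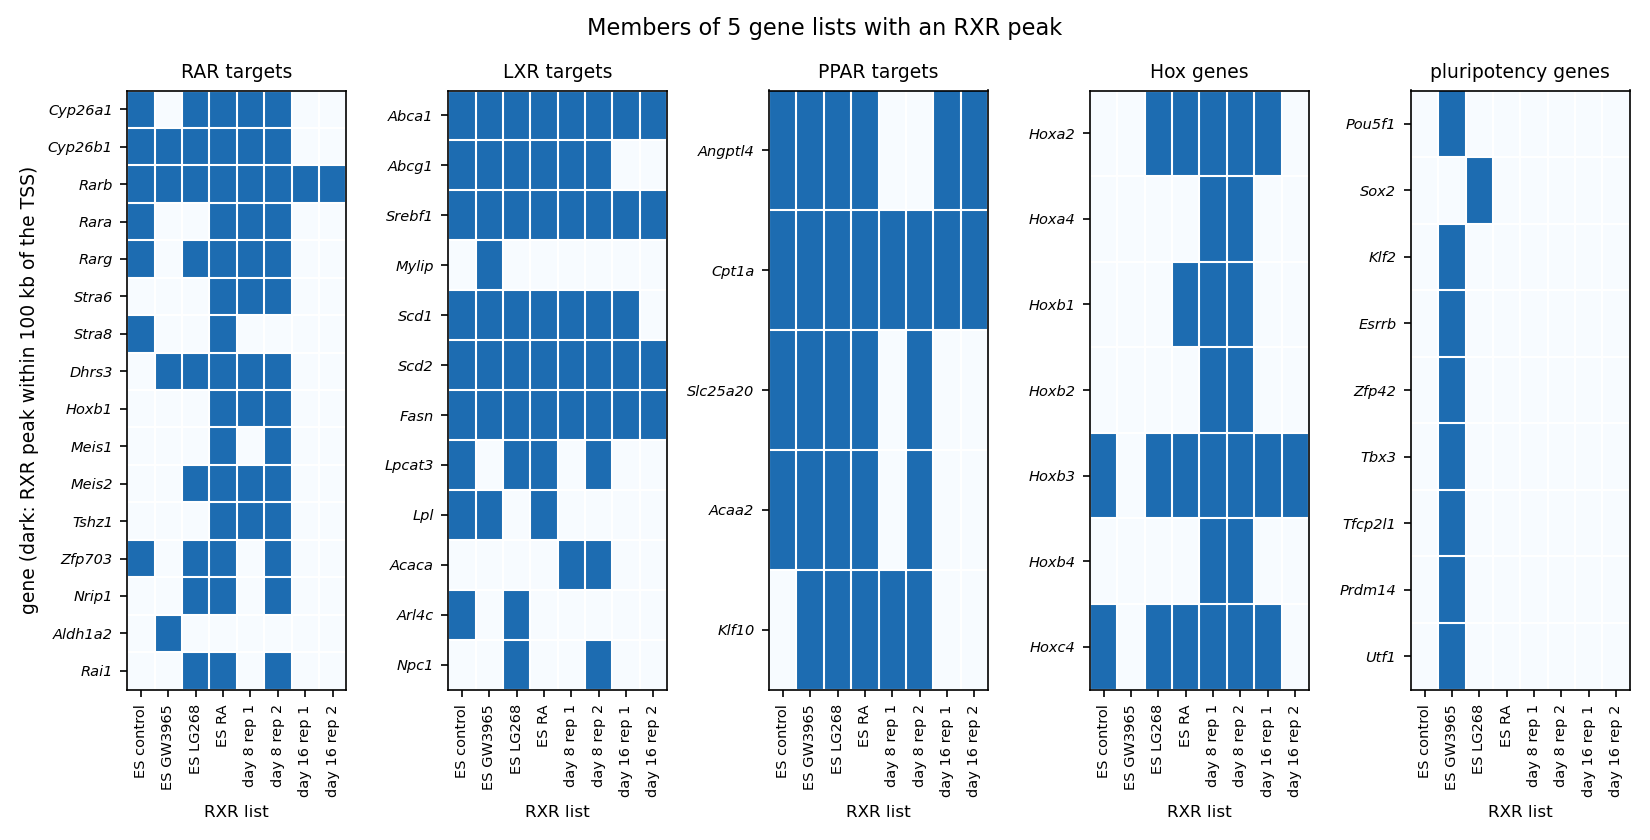
Members of 5 gene lists (rows) with an RXR peak within 100 kb of the TSS in each of the 8 RXR lists (columns), a filled cell marking a peak, and only genes named in the text with a peak in at least 1 list shown. Every RAR target shown but Aldh1a2 is filled in the RA column, the LXR targets Abca1, Srebf1, Scd2 and Fasn fill all 8 columns, and 8 pluripotency genes are filled with GW3965 alone.

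RXR peaks lay at promoters less often in the GW3965 list than in the others from ES cells. Within 1 kb of a TSS lay 26.6% of control peaks (exact 95% interval 24.0 to 29.4), 10.3% of GW3965 peaks (8.45 to 12.4), 28.2% of LG268 peaks (26.3 to 30.2) and 26.9% of RA peaks (24.9 to 28.9). By two-sided Fisher's exact test on peaks, which compares these lists and not the conditions, the odds ratio against the control was 0.317 for GW3965 (Benjamini-Hochberg adjusted p = 6.29e-21). By the same exact test it was 1.08 for LG268 (adjusted p = 0.418) and 1.01 for RA (adjusted p = 0.932). Introns held 33.4% to 36.5% of peaks in the 4 lists, and intergenic sequence 40.6% in the control and 53.0% with GW3965. At the differentiation days the promoter share was 10.3% and 16.7% in the day 8 replicates and 8.16% and 4.40% in the day 16 replicates, with odds ratios of 0.317, 0.554, 0.245 and 0.127 and adjusted p of at most 1.34e-10. Outside repeats the day 16 shares were 16.5% (11.8 to 22.2) and 8.78% (5.29 to 13.5), against 31.0% (28.0 to 34.1) in the control.

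RXR sites lay in acetylated chromatin far above chance in all 4 conditions, with the lowest share for GW3965. H3K27ac peaks of the same treatment covered 32.0% of control RXR peaks (exact 95% interval 29.2 to 34.8), 18.2% with GW3965 (15.8 to 20.8), 24.5% with LG268 (22.6 to 26.4) and 27.8% with RA (25.8 to 29.8). Random placement gave 0.690%, 0.548%, 0.379% and 0.478%. Against the control H3K27ac list, 33.7% of the LG268 RXR peaks were covered. GW3965 peaks shared with the control lay in control H3K27ac peaks at 49.6% (43.2 to 56.0) and those without a control peak at 9.08% (7.05 to 11.5). For LG268 these shares were 36.6% and 31.9%, and for RA 36.5% and 26.3%.

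The H3K27ac lists themselves were shorter with every ligand. The control list held 21418 H3K27ac peaks, the GW3965 list 17759, the LG268 list 12472 and the RA list 14958, or ratios to the control of 0.829, 0.582 and 0.698. Of the control peaks, 68.8% were found with GW3965, 51.8% with LG268 and 60.2% with RA. Conversely 83.1%, 91.3% and 88.0% of the ligand lists' peaks were found in the control. Promoter-near peaks made up 63.5% of the control list and 67.1%, 77.6% and 74.4% of the GW3965, LG268 and RA lists. An analysis chosen after seeing the data asked which gene lists lay near H3K27ac regions called in a single list. The 1797 RA peaks without a control peak lay near 11 of 21 RAR targets, against 3.06 by chance and 0 of 10000 random lists as high: Cyp26a1, Cyp26b1, Rarb, Rarg, Stra8, Dhrs3, Hoxb1, Meis1, Meis2, Tshz1 and Zfp703. Control peaks missing with RA lay near 10 of 21 RAR targets (1050 of 10000). Cyp26b1, Hoxb1, Meis1 and Meis2 were among them, so these genes have regions of both kinds.

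RXR peaks found with RA and absent from the control were set against gain and loss of H3K27ac peaks. Regions with an RA-only RXR peak were called in the RA H3K27ac list alone 33 times and in the control H3K27ac list alone 63 times, or 34.4% against 16.9% for regions without RXR (1710 and 8396). The odds ratio was 2.57 (two-sided Fisher's exact test on regions in these libraries, adjusted p = 0.000153 over 3 ligands). The 10 highest such gained regions lay nearest to Erdr1, Gm11202, Amz1, Nr2f2, AY512931, Camk2n1, Ier2, Gm16863, Tomm20 and Meis2, the last in intron 7 of 12 (chromosome 2, 116020800 to 116021260). For LG268 the counts were 13 and 112 (odds ratio 1.12, exact test, adjusted p = 0.645), with Tomm20, Camk1d, Erdr1, Tcf7l2, Thumpd3, Gm6567, Txndc2, Ptpla, Ap5z1 and Pcca at the highest gained regions. For GW3965 they were 5 and 16 (0.702, exact test, adjusted p = 0.645), at Myb, Gxylt1, Abcg1, Gm6567 and Urm1. All 3 results depended on the H3K27ac lists or on the background. With H3K27ac lists of equal length the RA odds ratio was 1.302 (Fisher's exact test, adjusted p = 0.767), and those of LG268 and GW3965 crossed 1, to 0.853 and 1.04. Without repeats that of GW3965 was 1.49. Against regions with RXR in both lists the odds ratios lay below 1 for every ligand, by the same exact test: 0.468 for RA (adjusted p = 0.0184), the opposite direction, 0.348 for LG268 (adjusted p = 0.0184), also the opposite direction, and 0.276 for GW3965 (adjusted p = 0.0475).

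**Figure D4:**
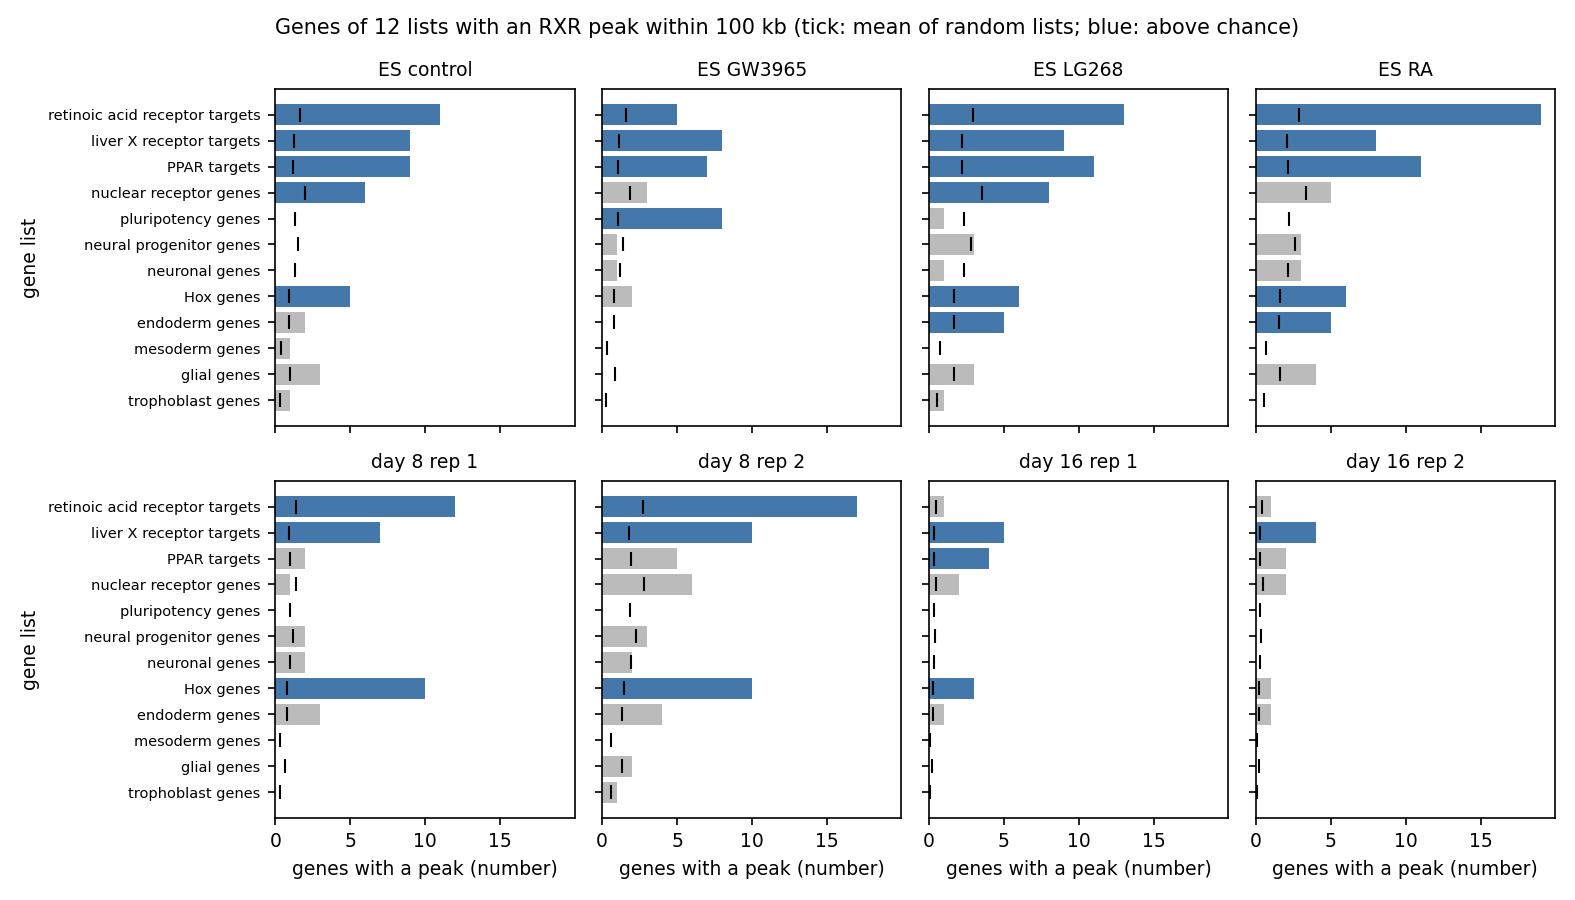
Number of genes of each of 12 gene lists (rows) with an RXR peak within 100 kb, per RXR list (panels), with the mean of 10000 random lists as a tick and lists above chance in blue. LXR targets are above chance in all 8 panels, RAR targets in the 4 ES and both day 8 panels, and pluripotency genes in the GW3965 panel alone.

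At day 8 of neural differentiation, RXR lay at RAR target genes and at genes of the Hoxa, Hoxb and Hoxc clusters. Of 21 RAR targets 12 had a peak in both replicates, and the replicates separately had 12 and 17, each with 0 of 10000 random lists as high. The highest regions outside repeats in both replicates were assigned to Dhrs3 (scores 132 and 156, 141663 bp from its TSS and so outside the 100 kb window), Rarb (109 and 137, chromosome 14, 16575380 to 16575731, at its promoter) and Cyp26b1 (119 and 125, chromosome 6, 84640551 to 84641104, intron 20 of 21 of an overlapping transcript). Aida, Ncoa3, Meis1 (270816 bp from its TSS), Fam171a1, Tbc1d14, D5Ertd579e and 4930524C18Rik completed the 10. The 10 highest regions of all at each day were (TTAGGG)n repeats. Hox genes had peaks at 10 of 17 genes in each replicate, against 0.764 and 1.43 by chance, with 0 of 10000 random lists as high. Among those in both were Hoxa2, Hoxa4, Hoxb2, Hoxb4 and Hoxc4, and Hoxa4, Hoxb2 and Hoxb4 had no peak in any ES list. Hoxa4 had its higher peak in intron 2 of 4 of an overlapping transcript, with scores of 44.6 and 68.0. LXR targets had peaks at 7 and 10 of 15 genes, with 0 of 10000 random lists as high in both, and Acaca, an acetyl-CoA carboxylase gene, had a peak in both replicates and in no ES list. Dcx, a gene of migrating neurons, also had a peak in both replicates and in no ES list (scores 5.57 and 11.9). The other lists did not pass in either replicate: PPAR (2 and 5 genes), nuclear receptor (1 and 6), neural progenitor (2 and 3), neuronal (2 and 2), endoderm (3 and 4), glial (0 and 2), trophoblast (0 and 1), pluripotency (0 and 0) and mesoderm (0 and 0).

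At day 16 few RXR peaks were called outside repeats, and LXR targets were the list above chance in both replicates in the main setting. With peaks within 10 kb, and without repeats, replicate 2 had 2 lists above chance. LXR targets had peaks at 5 and 4 of 15 genes, with 0 and 1 of 10000 random lists as high: Abca1, Fasn, Scd2 and Srebf1 in both replicates and Scd1 in replicate 1. PPAR targets had 4 genes in replicate 1 (3 of 10000) and 2 in replicate 2 (357), Angptl4 and Cpt1a in both. Of the RAR targets, Rarb alone had a day 16 peak (scores 15.2 and 15.5), against 0.474 and 0.450 genes by chance (3794 and 3658 of 10000). Of the 12 with a peak in both day 8 replicates, 11 had none. Over all genes the fall was also large, from 672 and 1281 genes with a peak in the day 8 replicates to 231 and 212 at day 16. Hox genes had 3 peaks in replicate 1 (16 of 10000) and 1, Hoxb3, in replicate 2 (2130). The replicate 1 call ended with peaks within 10 kb (1 gene). Nuclear receptor genes had 2 in each (Ncoa3 and Nr1d2), the endoderm list 1 in each (Dab2, in a simple repeat, and none outside repeats), and pluripotency, neural progenitor, neuronal, mesoderm, glial and trophoblast genes had none. The highest regions outside repeats in both replicates lay nearest to Aida (scores 75.5 and 81.6, chromosome 1, 183299119 to 183299598, intron 1 of 9), Nt5e (-231141 bp from its TSS), Ndufb3, Slc39a10 (-2028068 bp), Tbc1d14, Large, P4ha2, Fam171a1, D5Ertd579e and Dock2 (101972 bp). The regions of Aida, Fam171a1 and Dock2 lie in LTR elements, which are not counted as repeats here.

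The number of RXR peaks was 1599 ± 629 (SD, n = 2) at day 8 and 419 ± 14.1 (SD, n = 2) at day 16, a log2 ratio of -1.93. Outside repeats it was 1405 ± 624 (SD, n = 2) and 208.5 ± 4.95 (SD, n = 2), a log2 ratio of -2.75. Absent peak numbers made up 18.6% and 13.9% in the day 8 replicates and 38.0% and 38.2% at day 16. The highest peak numbers were 1418 and 2375 at day 8 and 692 and 662 at day 16. Part of the ratio may therefore come from the undescribed step that left peaks out. Median peak width was 182 and 203 bp at day 8 and 96 and 121 bp at day 16. Every day 16 list was shorter than every day 8 list, but the exact permutation test of 2 against 2 cannot go below p = 0.333. Peaks in both replicates merged to 981 regions at day 8 and 297 at day 16. Of the day 16 regions 88.9% (exact 95% interval 84.7 to 92.2) were found at day 8, and of the day 8 regions 30.0% (27.1 to 32.9) at day 16. The second share was 15.3% (12.9 to 18.0) outside repeats, 16.6% without day 8 replicate 1 and 54.8% with lists of equal length. Of the day 8 regions 53.2% (50.03 to 56.37) were found in the RA list of ES cells, 43.4% in the LG268 list, 36.2% in the control and 17.0% in the GW3965 list. With the 4 ES lists limited to 940 peaks each, these shares were 40.6%, 34.4%, 35.3% and 17.0%. Outside repeats and with the full ES lists, they were 46.1% for RA, 34.0% for LG268, 26.15% for the control and 8.84% for GW3965. Without day 8 replicate 1 the share found in the GW3965 list was 10.47%.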

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

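The test of LTR peaks by median score, and the later test of their share in the upper part of the list, were both chosen after the LTR result was seen. The other tests in this part were set out before their results were seen.

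LTR retrotransposon peaks stood out in the GW3965 RXR list because their share, 16.4% (exact 95% interval 14.1 to 18.9), lies above the interval of the control RXR list (2.48%, upper bound 3.59). Of the elements, RLTR13D6 held 23 GW3965 peaks, RLTR9D 11 and RLTR9E 10, against 0, 0 and 1 in the control. The same list alone had peaks at 8 pluripotency genes. Signal from active chromatin in general was tested on the GW3965 peaks without a control peak. Of these, 9.08% lay in control H3K27ac peaks, against 49.6% of shared peaks, where at least the share of shared peaks had been required. The test cannot exclude this source. Promoter position (7.35% against 18.7%) and score were not matched, and sites beside an H3K27ac peak were not counted. Sites present in every treatment but missed in shorter lists are argued against for the GW3965 peaks without a control peak. Of them, 13.7% (11.2 to 16.5) were found with LG268 or RA, where at least 50% had been required. Both tests took all 694 such peaks, 147 of them in LTR elements. They do not settle the LTR peaks or the peaks at pluripotency genes on their own.

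Weak peaks near the calling threshold remain a candidate explanation for part of the LTR peaks. The test set up for this used the median score percentile of the LTR peaks within their list, and at 42.9 (bootstrap 95% interval 37.7 to 49.2) it lay under the 50 set for weak peaks. That value is nearer the middle of the list than its lower end, and LTR peaks made up 19.15% of the lower part by score. Other GW3965 peaks without a control peak were not compared, so the test cannot place the LTR peaks near the threshold. A second test was added after the outcome of this median test was known. It asked whether weak peaks could be the only source, and found LTR elements at 13.6% (10.6 to 17.1) of the upper part of the GW3965 list by score, against 2.94% (1.69 to 4.73) in the control. Because the second test was chosen knowing the first, weak peaks are not ruled out here. A mixed or mislabelled library, or an antibody effect, was not tested and rests on 1 library, so no biological reading is offered.

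Simple repeats made up 37.1% and 37.9% of the day 16 replicate lists, flagged because both lie above the control interval (11.3%, upper bound 13.3). Satellites were flagged in the same way at 9.79% and 8.31% against 2.02%. These shares go with few peaks outside repeats, 212 and 205. A day 8 region called at day 16 had the higher day 8 score with probability 0.658 (bootstrap 95% interval 0.596 to 0.713), above the 0.5 set for lower depth or enrichment of the day 16 libraries. High peaks are kept more often under a loss of binding too, so this test cannot tell depth from such a loss. Whether day 16 has its own RXR sites stays undecided at 6.48% (2.65 to 12.9; 7 of 108 regions) against the 10% required, and a true loss of RXR binding stays open and untested.

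LINE peaks were flagged for lying above the control interval (1.01%, upper bound 1.80) at 3.73% and 3.18% in the day 8 replicates and 5.13% in day 16 replicate 2. Day 16 replicate 1, at 1.40% (0.515 to 3.02), does not lie above it.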

How the results depend on the processing

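Of 138 alternative values for the main results, 64 stayed the same, 67 moved, 1 was stronger, 1 was weaker and 5 reversed, all H3K27ac odds ratios. Of 368 others, 336 stayed the same, 15 moved, 10 were weaker and 7 stronger. The cause was not tested.

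Leaving out repeats, ES lists of equal length in the day comparison, equal lists and reciprocal overlap for H3K27ac overlap, and the crossed block were chosen after the data were seen. With equal lists, control RXR peaks were found at 25.4% with GW3965, 58.2% with LG268 and 57.2% with RA, and LG268 peaks at 59.6% with RA. Promoter shares were 25.4% for LG268 and 23.5% for RA. At 50% reciprocal overlap, 64.8% of control peaks were found with LG268 and 66.6% with RA, and 50.9% of LG268 peaks with RA. Against random control H3K27ac centres the excess was 32.8 times for GW3965, 28.8 for LG268, 33.4 for RA and 24.5 for LG268 in RA.

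Without repeats, control peaks were found at 16.2% with GW3965, 67.7% with LG268 and 66.9% with RA, and LG268 peaks at 50.6% with RA. Peaks without a control peak made up 82.0% of GW3965, 67.0% of LG268 and 65.3% of RA lists. Promoter shares were 31.0% for the control, 30.8% for LG268 and 29.5% for RA, and 13.0% of GW3965 and 25.8% of RA RXR peaks lay in H3K27ac peaks.

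At the stricter threshold, peaks without a control peak made up 63.0% (GW3965), 54.8% (LG268) and 53.7% (RA). With ligand lists limited to the control's number they made up 43.9% (LG268) and 43.4% (RA). Promoters within 5 kb held 37.0% of control, 21.1% of GW3965, 36.7% of LG268 and 36.1% of RA peaks. In control H3K27ac peaks lay 33.7% of LG268 and 30.4% of RA RXR peaks, and with equal H3K27ac lists 25.8% of control and 25.5% of RA. Within 1000 bp of an H3K27ac peak lay 46.6% (control), 32.1% (GW3965), 35.9% (LG268) and 40.8% (RA).

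Against regions with RXR in both lists, the H3K27ac odds ratios (Fisher's exact test) were 0.276 for GW3965 (adjusted p = 0.0475), 0.348 for LG268 (adjusted p = 0.0184) and 0.468 for RA (adjusted p = 0.0184), the last 2 reversed. With equal H3K27ac lists the RA odds ratio was 1.302 (exact test, adjusted p = 0.767), and those of GW3965 and LG268, at 1.04 and 0.853, crossed 1 without a call, as did GW3965 without repeats at 1.49. With equal H3K27ac lists, control H3K27ac peaks were found at 80.1% with GW3965, 75.5% with LG268 and 77.7% with RA. At 50% reciprocal overlap these were 58.3%, 42.3% and 50.7%.

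For the days, leaving out repeats gave a log2 ratio of -2.75, with 83.3% of day 16 regions found at day 8 and 15.3% the other way. At 50% reciprocal overlap these shares were 65.6% and 26.4%. With equal lists they were 72.3% and 54.8%, and equal lists give no ratio. Leaving out 1 replicate at a time gave ratios from -2.29 to -1.46, day 16 shares from 76.3% to 85.9% and day 8 shares from 16.6% to 27.4%. The replicate block, which pairs lists that share only a number, gave -1.87, 71.7% and 19.1%, and across 232 regions the replicate differences of the days had r = -0.102. With the replicate numbers crossed the values were -1.87, 73.8% and 19.5%.

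Of 96 gene list calls 30 were above chance. Of these, 25 held with peaks within 10 kb (27 calls in all), 28 at any distance (31), 28 with equal lists (29) and 29 without repeats (30). Day 16 replicate 2 had 2 lists above chance within 10 kb and 2 without repeats. Calls were lost for nuclear receptor genes in the control, RAR targets with GW3965, endoderm genes with LG268 and RA, and Hox genes in day 16 replicate 1.

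Equal lists do not apply to the shortest lists. For the gene list calls they left the GW3965 list and both day 16 lists unchanged. The calls of these lists (4, 3 and 1) are among the 28 that held with equal lists and were not put to a test there. The direct-repeat alternatives (half-site RGKTSA, window of 50 bp) were not run. Depth is unknown, so list length limits every overlap and every count of genes.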

Other observations

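The gene list results in this part were chosen after the data were seen, and the tests of the LG268 H3K27ac list were set out before their results were seen.

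Among H3K27ac regions called in a single list, the 3001 GW3965 peaks without a control peak lay near 8 of 20 pluripotency genes, against 3.17 by chance with 65 of 10000 random lists as high: Pou5f1, Nanog, Klf2, Klf4, Klf5, Esrrb, Zfp42 and Nr5a2. Control peaks missing from the GW3965 list lay near 11 of 20 pluripotency genes (785 of 10000), Pou5f1, Nanog, Klf2 and Esrrb among them, so these 4 have regions of both kinds. The GW3965 regions also lay near 7 of 15 LXR targets (145 of 10000), Abca1, Abcg1, Mylip, Scd2, Fasn, Lpl and Npc1, and 6 of 12 glial genes (119). Control peaks missing from the GW3965 list lay near 12 of 19 PPAR targets (7 of 10000) and 9 of 12 glial genes (45). Control peaks missing with LG268 lay near 13 of 21 RAR targets (34) and 11 of 17 Hox genes (90), and those missing with RA near 11 PPAR targets (168) and 10 Hox genes (78). With the RAR targets near RA regions, these are the lists above chance among 72 such tests, without adjustment.

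The LG268 H3K27ac list was the shortest, with 12472 peaks against 21418 in the control. Lower depth or enrichment is consistent with the finding that a control peak kept with LG268 had the higher control score with probability 0.873 (bootstrap 95% interval 0.868 to 0.877). Selective loss across all LG268 RXR sites is argued against for peaks of similar control score. Within control score deciles, the Mantel-Haenszel odds ratio of a peak being missing with an LG268 RXR peak was 0.571 (0.462 to 0.705). Promoter position was not matched, and the test did not separate LG268-only sites from sites with RXR in the control too. For LG268-only sites, the odds ratio of H3K27ac gain over loss was 1.12 against regions without RXR. It was 0.348, toward loss, against regions with RXR in both lists. Selective loss at LG268-only sites therefore stays open. A general fall in acetylation with LG268 stays open, since 1 library cannot separate it from depth.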
